A study of Mus musculus with 12 samples.

How the data were processed

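RNA abundance was measured on 12 Mouse Gene 1.0 ST arrays. Per the labels' protocols, 18 mice of both sexes, 7 to 12 weeks old, were each kept in a clean air chamber for 40 hours at a flow of 3.1 L per minute. From 26 hours on, they received filtered air alone or odorant for 10 seconds every 20 minutes. The odorant was a citrus accord, named in the series title with 5%, and its composition is not given in the sources used here. The olfactory mucosa was dissociated and sorted by fluorescence into GFP-positive and GFP-negative cells, with 3 mice per sample, and biotinylated cRNA was made from total RNA. Which mice of which sex went into which pool is not given in the sources used here.

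The log2 values per probe set were deposited by the authors, who made them with Affymetrix Expression Console per the submitters' processing notes. Its version, the summarization algorithm and the background method are not given in the sources used here. The log2 scale was read from the values, which are not whole numbers and lie between 2.42 and 14.1. The quartiles of the 12 arrays are close to one another but not identical, and how the arrays were scaled to one another before deposit is not given in the sources used here. Values were not centred per gene. They were used as deposited. The table holds 12 arrays and 0 columns of other samples.

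Of 35556 probe sets, 23410 had a gene in the annotation used, 21789 of these had 1 symbol and 1621 had several. The other 12146 had no symbol in that annotation. Probe sets with several symbols or none were left out of the tests, because their signal belongs to no single gene. Among probe sets with 1 symbol 21698 gene identifiers matched the gene reference and 91 did not, and 0 symbols were updated. For the 999 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which left 19938 genes, 1015 of them odorant receptors. No filter on low values was applied. Arrays of 1 group correlated with r between 0.984 and 0.994, and arrays of different fractions between 0.929 and 0.960. No pair of arrays shared more than 11 identical values. The first principal component, which separated the fractions, held 88.8% of the variance and the second 2.84%. Signal intensity gives no count, so no depth per array can be given, and the number of arrays limits the precision.

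The 4 groups were odor GFP-positive, odor GFP-negative, vehicle GFP-positive and vehicle GFP-negative, with 3 arrays each. They were fitted in 1 linear model in limma 3.58.1 under R 4.3.3, without a replicate block, with moderated two-sided tests and Benjamini-Hochberg adjustment at 0.05. Differences are log2 with the standard error (SE) of the fit, and means carry the SD of 3 arrays. The 5 comparisons were odor minus vehicle in GFP-positive and in GFP-negative cells, GFP-positive minus GFP-negative cells in vehicle and in odor mice, and the interaction of both. Odorant receptors were adjusted over all genes and over their own list. Shifts of 29 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

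The lists, the comparisons and their tests, the rule for naming genes and all alternatives but those stated as added were chosen before the data were examined. The rule drops symbols of predicted genes, small RNA genes and mitochondrial genes. It names odorant receptors past 0.05 over their list whose groups do not overlap, up to 15 with the largest rise and 5 with the largest fall, or the 5 with the smallest p where fewer than 5 pass. It names the 10 other genes with the largest rise and the 10 with the largest fall past 0.05 over all genes. It always names S100a5, Omp, Kirrel2, Kirrel3, Fos and Egr1, and of each list up to 4 members with the largest difference among those called, or the 2 with the smallest p. The texts give part of the genes so named. Outside the rule in at least 1 comparison where they appear are Npas4, Gap43, Dcx, Tubb3, Foxj1, Dcdc2a, Ncmap, Cbx5, Atp5g2, Cox6b2, Cox6a2, Ms4a10, Cnga3, Nqo1 and Rasgrp4, which were chosen after their values were seen.

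The lists covered odorant, trace amine and vomeronasal receptors, activity-dependent and low-activity genes, immediate early, heat shock and unfolded protein response genes. Further lists held genes of mature and immature neurons, progenitors, horizontal basal, sustentacular, Bowman's gland, microvillous, respiratory, ensheathing glia, endothelial and fibroblast cells, of myeloid cells, neutrophils, lymphoid and erythroid cells, and of guanylyl cyclase D neurons. The rest held biotransformation, axon guidance and identity, receptor choice, ribosomal protein and respiratory chain genes. Some genes are on 2 lists. The activity list shares 3 genes with the axon guidance list, which shares 1 with the low-activity list and 1 with the biotransformation list. The receptor choice list shares 3 with the mature neuron list and 1 with the unfolded protein response list. The sustentacular list shares 4 with the biotransformation list, and the lymphoid list shares 1 with the guanylyl cyclase D list.

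Fractions sorted from 1 pool were matched by the title's replicate number. After removal of group means over all genes, the fractions of 1 pool correlated with r of 0.252, 0.172 and 0.124 in odor mice and of 0.113, 0.0732 and 0.111 in vehicle mice, and 12 of 12 arrays were closest to their own pool among the other fraction's arrays of that treatment. The number in the bracketed sample code pairs odor with vehicle arrays otherwise than the title number does. Pairs by code gave 0.309, 0.185 and 0.268 in GFP-positive cells, where 6 of 6 arrays were closest to their partner, and 0.439, -0.206 and 0.281 in GFP-negative cells, where 3 of 6 were. Pairs by title number gave -0.171 and 0.268 in GFP-positive and 0.244 and 0.281 in GFP-negative cells. All sample codes carry the same date, and the labels name no batch.

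The alternatives were a second quantile normalization, median centring, cyclic loess, receptors centred on their own median, filters that drop the genes lowest in value or the genes under the table median in all groups, the 2 groups compared alone, array weights, a mean-variance trend, robust moderation, replicate blocks by title number, code number or pool, every probe set instead of 1 per gene, a threshold of 0.10 and each array left out. Added after the data were seen were the GFP-positive arrays alone with the code number as block, and cyclic loess for the list tests.

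The procedure was tested on simulated data with the spread of these arrays, in which 200 of 19938 genes were changed in 10 simulations. Between odor and vehicle in GFP-positive cells it called 63.4% of genes changed by 0.5 and 93.6% of those changed by 1, and among receptors, over their list alone, 16.7% and 56%. For the interaction it called 27.6% and 84%. Between 4.62% and 6.01% of calls were false over the 5 comparisons. A list shifted by 0.3 was called in 10 of 10 simulations, and between 0.1 and 0.3 other lists per simulation. The simulated noise was drawn for each gene alone, with 1 spread for all arrays. It therefore cannot show how the list tests fare where genes vary together, or where the fractions differ in spread. Recovery with fewer changed genes was not simulated. Relations across arrays were tested by permutation.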

Results

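Gene expression was measured on 12 arrays of cells sorted from the olfactory mucosa of 18 S100a5-tauGFP mice. In these mice a fluorescent protein marks cells that use S100a5, a gene for a calcium-binding protein whose transcription in olfactory sensory neurons depends on their activity. Mice breathed filtered air alone (vehicle) or filtered air with short pulses of a 5% citrus accord, a perfumer's blend. Each of 6 pools of 3 mice, 3 pools per treatment, gave 1 array of GFP-positive and 1 array of GFP-negative cells. The 4 groups therefore hold 3 arrays each, and the tests of odor against vehicle compare pools of mice. Those of the sort compare the fractions of the same 3 pools, fitted without the pairing, and list tests compare the genes of a list with all others. The median deposited value of an array lay between 7.04 and 7.20 (log2), and values ranged from 2.42 to 14.1. Odorant receptors had array medians of 7.50 to 7.73 in GFP-positive cells and of 6.61 to 7.23 in GFP-negative cells. The number of arrays limits the precision: the median standard error of an odorant receptor's difference between 2 groups was 0.221, against 0.0968 over all genes.

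The comparison of odor with vehicle mice among GFP-positive cells asks which receptor transcripts are more abundant in cells with the activity reporter when the accord is given. Olfr747, an odorant receptor gene (probe set 10419456), rose from 6.14 ± 0.24 in vehicle mice to 7.71 ± 0.30 in odor mice (log2, SD, n = 3 arrays each). This was a 2.96-fold rise (log2 difference 1.57, SE 0.17), with an adjusted p of 0.0152 over all genes by limma and of 0.000775 adjusted over the list alone. The 3 arrays of odor mice lay between 7.51 and 8.05 for Olfr747, and the 3 of vehicle mice between 5.88 and 6.33. Olfr1280, another odorant receptor gene (probe set 10474485), fell by 0.96 (SE 0.15), from 5.92 ± 0.29 to 4.96 ± 0.28 (SD, n = 3). Its adjusted p was 0.0214 adjusted over the list alone and 0.421 over all genes. Its values in odor mice, 4.75 to 5.28, lie below the lower quartiles of those arrays, 5.75 to 5.78. The size of this fall is therefore uncertain.

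Of 1015 odorant receptors, 1 rose and 1 fell adjusted over the list alone. Over all 19938 genes 1 receptor rose and 0 fell, and no gene besides Olfr747 passed in limma. Unadjusted p-values under 0.05 numbered 259 over all genes, where chance gives 996.9, and 32 over the receptors, where chance gives 50.75. Fitting the 2 groups alone, without the spread shared by all 4, gave 660 and 73. The receptor count was 31 to 34 with the 3 other scalings. Replicate blocks in all arrays gave 45 by code number and 53 by title number. Array weights gave 93, and the code-number block on the GFP-positive arrays alone, added after the data were seen, gave 143. The number of receptors under 0.05 thus depended on the fit. The receptors next in line did not pass: Olfr1308 differed by -0.64 (SE 0.16), Olfr1204 by -0.85 (SE 0.22) and Olfr618 by -0.59 (SE 0.16). Groups did not overlap for 7.93% of genes, and chance gives 10%. Receptor genes are close paralogues, and probes that bind more than 1 of them make single receptor values uncertain. The call of Olfr747 over all genes ended with cyclic loess scaling, with the 2 groups fitted alone, and with the title number as a replicate block. It also ended with the number in the sample code as a block on the GFP-positive arrays alone, an alternative added after the data were seen. That fit called 0 genes and 5 receptors, 4 higher and 1 lower: Olfr747, Olfr814, Olfr183, Olfr1284 and Olfr1200, the latter 4 named after their values were seen, and not Olfr1280. The call over all genes ended as well without replicate 3 or 4 of the odor arrays or replicate 1 or 4 of the vehicle arrays. Over the receptor list it held in each of 14 alternatives (highest adjusted p 0.0201). Olfr1280 lost its call in 6 of 13 (highest adjusted p 0.157) and when receptors were centred on their own median (adjusted p 0.999). Among the 6 were the fits without odor replicate 2 or 4 and without vehicle replicate 1 or 2.

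**Figure D1:**
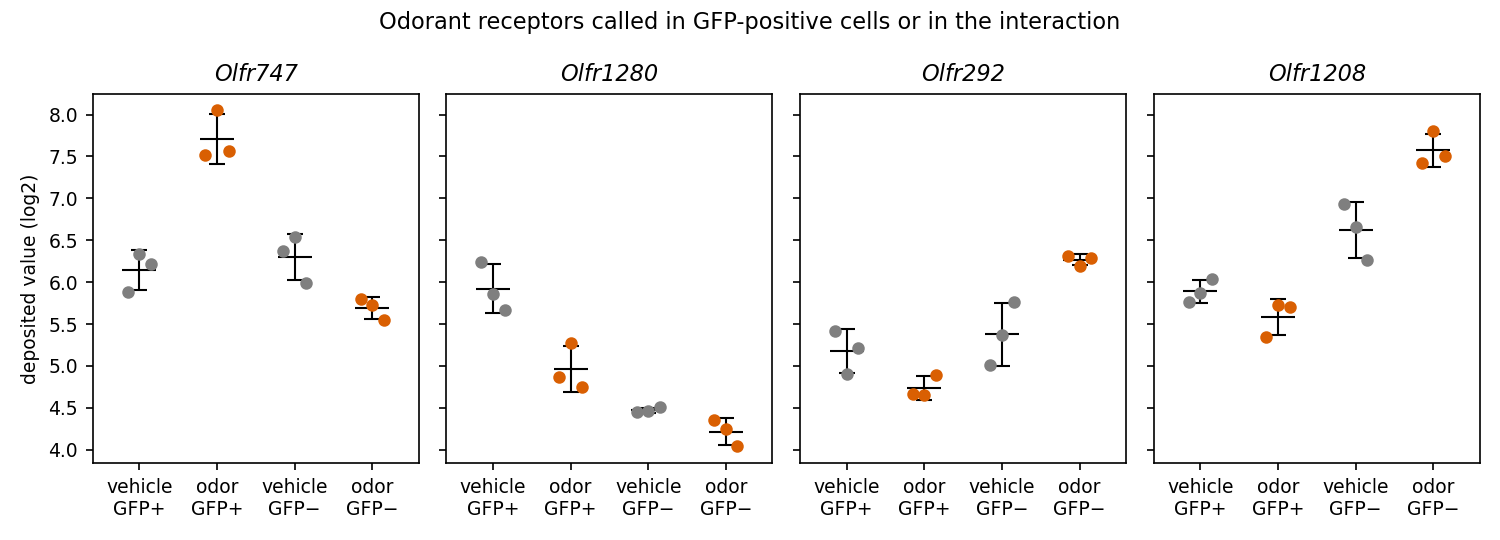
Deposited log2 values (vertical axis) of 4 odorant receptors in the 4 groups of sorted cells, with 1 point per array and black marks for the mean and SD of 3 arrays. Olfr747 lay at 7.51 to 8.05 in GFP-positive cells of odor mice and at 5.88 to 6.33 in those of vehicle mice, and Olfr1280 had means of 4.96 and 5.92 in the same groups.

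Genes that follow neuronal activity gave small differences between odor and vehicle in GFP-positive cells, and none of them passed over all genes. S100a5 itself differed by -0.00 (SE 0.10), and Omp, which encodes the olfactory marker protein of mature neurons, by 0.01 (SE 0.08). Both groups were sorted for the S100a5 reporter, which can limit how far S100a5 and genes that vary with it differ between them. Kirrel2 and Kirrel3, adhesion genes that active and inactive sensory neurons express in opposite amounts, differed by 0.09 (SE 0.14) and -0.06 (SE 0.13). The immediate early genes Fos and Egr1, which stimulated cells switch on, differed by -0.29 (SE 0.33) and -0.24 (SE 0.29).

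As a group the 11 genes of the activity-dependent list were higher in odor mice among GFP-positive cells (median 0.07, 9 of 11 above 0, adjusted p = 0.0311, and adjusted p = 0.98 with an estimated correlation). Pcdh10, a protocadherin that responds to neuronal activity, differed by 0.40 (SE 0.10) and passed adjusted over the list alone but not over all genes. Rasgrp4, a guanine nucleotide exchange factor gene, differed by 0.30 (SE 0.14) and did not pass. The odorant receptors as a group were lower (median -0.05, but 0.01 with the title number as a replicate block, 382 of 1015 above 0, adjusted p = 0.00285, and adjusted p = 0.98 with an estimated correlation). The 12 neutrophil genes were higher (median 0.19, 11 of 12 above 0, adjusted p = 0.0251, and adjusted p = 0.98 with an estimated correlation). Their members Lcn2 and Ltf, genes of granule proteins, differed by 0.49 (SE 0.34) and 0.37 (SE 0.24), neither past the test alone. The 61 ribosomal protein genes were higher by a median of 0.03 (45 of 61 above 0, adjusted p = 0.0242, and adjusted p = 0.98 with an estimated correlation). No other list passed, among them trace amine receptors, where Taar8c differed by 0.55 (SE 0.26), and biotransformation enzymes, where the alcohol dehydrogenase Adh1 differed by 0.13 (SE 0.08). The receptor call ended without odor replicate 3 or vehicle replicate 4 (adjusted p up to 0.130), and the activity call without any GFP-positive array but vehicle replicate 2 (up to 0.321). The neutrophil call ended without odor replicate 4, where the median was -0.02, or vehicle replicate 1 or 2 (up to 0.592). The ribosomal call ended without replicate 2 or 4 of either group (up to 0.683). Medians with 1 array left out ranged from -0.08 (odor replicate 2) to -0.03 (odor replicate 3) for the receptors, from -0.02 to 0.59 (odor replicate 2) for the neutrophil list and from -0.00 (odor replicate 2) to 0.08 (odor replicate 3) for the ribosomal list, and the neutrophil median was 0.11 without vehicle replicate 1 and 0.34 without vehicle replicate 4.

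The same comparison among GFP-negative cells shows what the exposure changes in cells without the reporter. No gene and no odorant receptor passed (0 in limma), with a smallest adjusted p of 0.732 over all genes. Unadjusted p-values under 0.05 numbered 1301, where chance gives 996.9. Fitting the 2 groups alone, without the spread shared by all 4, gave 520, so the excess depends on that shared spread. Olfr1208 (probe set 10484764) was 7.58 ± 0.20 in odor mice and 6.62 ± 0.33 in vehicle mice (SD, n = 3), a difference of 0.96 (SE 0.16, adjusted p = 0.0713 adjusted over the list alone). Olfr292 (probe set 10554733) was 6.26 ± 0.07 and 5.38 ± 0.38 (SD, n = 3), a difference of 0.89 (SE 0.17, adjusted p = 0.0961 adjusted over the list alone). Olfr51 differed by 0.81 (SE 0.20), Olfr1198 by 0.93 (SE 0.24) and Olfr960 by 0.56 (SE 0.15), also without passing. With the title number as a replicate block 4 receptors were called higher, Olfr1198 among them, with Olfr994, Olfr1243 and Olfr895, which were named after their values were seen. The activity marker S100a5 differed by -0.12 (SE 0.10), Kirrel2 by -0.01 (SE 0.14), Fos by -0.08 (SE 0.33) and Egr1 by -0.15 (SE 0.29). Omp differed by -0.01 (SE 0.08) and Kirrel3 by 0.04 (SE 0.13). Groups did not overlap for 7.44% of genes, and chance gives 10%. Without odor GFP-negative replicate 2, 15 genes and 5 receptors passed, without replicate 3 of that group 3 and 2, and without replicate 4 of that group 1 and 1. Without vehicle GFP-negative replicate 1, 1 receptor passed, and without replicate 4 of those, 2 did. Olfr1208 passed without odor replicate 2 or vehicle replicate 1 (lowest adjusted p 0.0220) and Olfr292 without vehicle replicate 4 (adjusted p 0.0162).

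Several gene lists were nevertheless called in GFP-negative cells, each with an adjusted p = 0.86 with an estimated correlation. The 39 leukocyte genes had a mean difference of 0.193 (SE 0.165), within 2 standard errors of 0. Their means followed a split of the arrays that crosses treatments: 10.4 in each of odor replicate 2 and vehicle replicates 1 and 2, against 10.7, 10.9 and 10.6 in odor replicates 3 and 4 and vehicle replicate 4. Receptor medians ran the other way, with 7.23, 7.00 and 7.00 against 6.76, 6.73 and 6.61, and that split called 1939 genes. The 10 lymphoid genes had a median of 0.17 (7 of 10 above 0, adjusted p = 0.0055), the 12 neutrophil genes of 0.15 (12 of 12 above 0, adjusted p = 0.0182) and the 17 macrophage and myeloid genes of 0.17 (15 of 17 above 0, adjusted p = 0.0372). Jchain, which encodes the joining chain of secreted antibodies, differed by 0.86 (SE 0.22), and Nkg7, a granule gene of cytotoxic lymphocytes, by 0.50 (SE 0.11). Both passed adjusted over the list alone but not over all genes. Mpo and Elane, enzymes of neutrophil granules, differed by 0.57 (SE 0.22) and 0.53 (SE 0.29), and the macrophage receptor gene Adgre1 by 0.35 (SE 0.24). Dividing-cell and progenitor genes were higher (median 0.14, 11 of 14 above 0, adjusted p = 0.0116), with the mitotic genes Bub1 at 0.31 (SE 0.16) and Ccnb2 at 0.40 (SE 0.22). Ribosomal protein genes were higher too (median 0.11, 56 of 61 above 0, adjusted p = 3.5e-09), with Rpl36a at 0.24 (SE 0.10). The guanylyl cyclase D and necklace list was higher (median 0.28, 12 of 16 above 0, adjusted p = 0.0372). Most of its members are of the Ms4a family, which leukocytes also express. Ms4a6d differed by 0.48 (SE 0.17), whereas the cyclic nucleotide channel gene Cnga3 differed by -0.24 (SE 0.07). The odorant receptors were higher as a group (median 0.04, 562 of 1015 above 0, adjusted p = 0.0372). Vomeronasal receptors were lower (median -0.06, 51 of 165 above 0, adjusted p = 0.0372), with Vmn2r74 at -0.34 (SE 0.13).

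The lymphoid, progenitor and ribosomal lists kept their calls with cyclic loess scaling, an alternative added after the data were seen, and the other 5 lost theirs. The macrophage, guanylyl cyclase D and vomeronasal lists lost their calls with a second quantile normalization too. Only the lymphoid and ribosomal lists kept theirs when the genes lowest in value were dropped. Without odor GFP-negative replicate 4 the adjusted p was 0.907 for the macrophage list (median 0.01), 0.213 for the neutrophil list (0.04), 0.387 for the lymphoid list (-0.04), 0.443 for the guanylyl cyclase D list (0.12) and 0.0723 for the ribosomal list (0.04). All of these but the ribosomal list also lost their calls without vehicle GFP-negative replicate 1, with medians of 0.05 for the lymphoid and 0.18 for the guanylyl cyclase D list. Odor replicate 3 and vehicle replicate 2 each ended the macrophage, neutrophil and guanylyl cyclase D calls, with medians of 0.14 for the guanylyl cyclase D list without the former and 0.07 for the neutrophil list without the latter. The progenitor call ended without odor replicate 3 (adjusted p 0.485, median 0.05), odor replicate 4 (0.09) or vehicle replicate 1 (0.05). The vomeronasal call ended without any array but vehicle replicate 2 (adjusted p up to 0.538), its median was -0.03 without replicate 4 of either group, and with cyclic loess it was -0.00 and with a second quantile normalization -0.01. The highest medians of the progenitor (0.29), macrophage (0.29), neutrophil (0.28), lymphoid (0.34) and ribosomal (0.18) lists came without odor replicate 2. Without vehicle replicate 4 the neutrophil median was 0.25 and the lymphoid median 0.28. The direction of the odorant receptors did not hold, and 4 of 6 fits with 1 array left out kept the upward call. Their median was -0.08 without odor replicate 2, -0.07 without vehicle replicate 4, where the call ended (adjusted p 0.426), and -0.07 with array weights. It lay between 0.08 and 0.10 without any 1 of the other 4 arrays, and was 0.05 with a second quantile normalization, 0.07 with cyclic loess and 0.08 with the title number as block.

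The comparison of GFP-positive with GFP-negative cells shows what the sort separates, in vehicle mice and in odor mice. Odorant receptors were mostly higher in GFP-positive cells. In vehicle mice 610 of 1015 were higher, 113 were lower and 292 did not pass, and in odor mice the numbers were 579, 126 and 310. With receptors centred on their own median, which removes any shift they share, the balance turned to 258 higher and 327 lower in vehicle mice and 257 and 283 in odor mice, adjusted over the list alone. Adjusted over the list alone they were 625 higher and 117 lower in vehicle mice, and 598 higher and 132 lower in odor mice. The median receptor was higher by 0.76 in vehicle mice (adjusted p = 1.1e-08) and by 0.66 in odor mice (adjusted p = 7.3e-05). These had an adjusted p = 0.31 and an adjusted p = 0.46 with an estimated correlation. Olfr472 rose from 4.42 ± 0.78 to 8.28 ± 0.05 (SD, n = 3) in vehicle mice (difference 3.86, SE 0.36) and by 3.93 (SE 0.36) in odor mice. The 4.42 lies below the lower quartiles of the vehicle GFP-negative arrays, 5.65 to 5.83, so the size of this rise is uncertain. Olfr1099 was higher by 3.72 and 3.63 (SE 0.35), Olfr849 by 3.64 and 3.51 (SE 0.22) and Olfr309 by 3.55 and 3.78 (SE 0.26) in vehicle and odor mice. At the other end Olfr1297 had differences of -4.38 and -4.73 (SE 0.35), Olfr77 of -4.10 and -3.71 (SE 0.21). Olfr460 had -3.93 in vehicle mice (SE 0.34) and Olfr393 had -3.81 in odor mice (SE 0.22).

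The receptor enrichments of vehicle and odor mice went together, with a Pearson r of 0.965 and a Spearman rho of 0.950 across 1015 receptors, which are not independent replicates. In both treatments 536 receptors were higher, where 348 would be shared by independent draws, and 105 were lower, where 14 would be. The receptor pseudogene Olfr106-ps was higher by 3.40 in vehicle mice and 3.34 in odor mice (SE 0.24). Trace amine receptors, a second family of olfactory receptors, split. Of 12, 6 were higher and 1 was lower in vehicle mice, and 4 and 1 in odor mice, without a call for the list (adjusted p = 0.28 and adjusted p = 0.29). Taar4 was higher by 1.75 and 1.57 (SE 0.30) and Taar9 by 1.50 and 1.59 (SE 0.32), whereas Taar2 differed by -1.92 and -1.26 (SE 0.32).

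**Figure D2:**
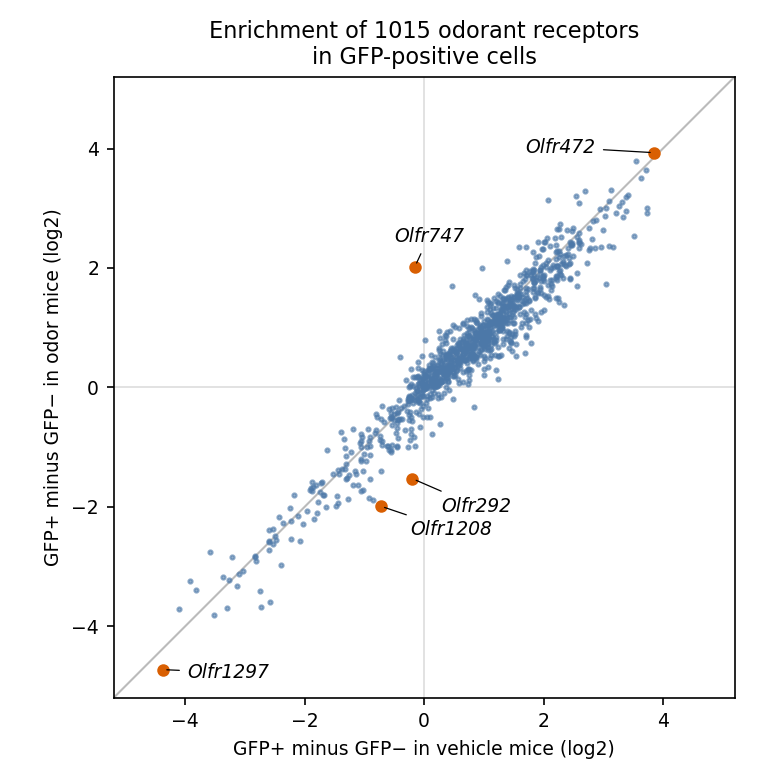
Each point is 1 of 1015 odorant receptors, placed by its GFP-positive minus GFP-negative difference (log2) in vehicle mice (horizontal axis) and in odor mice (vertical axis), with the diagonal marking equal differences. The points follow the diagonal (Pearson r 0.965), and Olfr747 stands off it with -0.16 in vehicle mice and 2.02 in odor mice.

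Genes of mature sensory neurons were higher in GFP-positive cells, where 16 of 17 rose and 0 fell in each treatment. Their medians were 0.50 in vehicle mice and 0.59 in odor mice, and 0.25 and 0.28 with cyclic loess (adjusted p = 2.1e-05 and 0.00014, and adjusted p = 0.32 and adjusted p = 0.40 with an estimated correlation). The phosphodiesterase Pde1c rose by 0.86 and 0.93 (SE 0.12), the chloride channel Ano2 by 0.79 and 0.77 (SE 0.11) and the exchanger Slc24a4 by 0.79 and 0.74 (SE 0.12), all of them parts of odor transduction. Omp was near the top of the array's range in every group, at 13.48 ± 0.03 in GFP-positive and 13.16 ± 0.11 in GFP-negative cells of vehicle mice (SD, n = 3). It rose by 0.31 and 0.33 (SE 0.08), and cyclic loess left 0.04 and 0.00, without a call. Immature neurons' genes split into 6 higher and 7 lower of 15 in each treatment (medians -0.19 and -0.13, the second of them 0.01 with median centring). As a list they did not pass (adjusted p = 0.087 and 0.086). The list was called lower in vehicle mice with each of the 3 other scalings (adjusted p 0.0421 with cyclic loess) and without GFP-negative replicate 4, and in odor mice with median centring and without GFP-negative replicate 3.

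Activity-dependent genes were higher in GFP-positive cells. In vehicle mice 8 of 11 rose, in odor mice 9 of 11, and 2 fell in each. Their medians were 1.00 and 1.02 (adjusted p = 0.012 and 0.018, and adjusted p = 0.30 and adjusted p = 0.33 with an estimated correlation). Lrrc3b, a leucine-rich repeat gene, rose by 1.36 and 1.40 (SE 0.11), Kirrel2 by 1.25 and 1.35 (SE 0.14) and Pcdh10 by 1.23 and 1.43 (SE 0.10). The members that fell were Calb2, which encodes the calcium buffer calretinin, with -1.88 and -1.80 (SE 0.09), and Rasgrp4, with -0.79 and -0.70 (SE 0.14). S100a5, the gene of the reporter locus, rose by 0.31 in odor mice (SE 0.10, adjusted p = 0.0166) and differed by 0.19 in vehicle mice (SE 0.10, adjusted p = 0.12). Its call was lost with cyclic loess and without odor GFP-positive replicate 2 or odor GFP-negative replicate 4. Genes of low-activity neurons rose as well, 4 of 4 in each treatment (medians 0.61 and 0.59, and 0.32 and 0.30 with cyclic loess, adjusted p = 0.020 and 0.051, and adjusted p = 0.30 and adjusted p = 0.39 with an estimated correlation). Cd36, a fatty acid receptor gene, rose by 0.98 and 0.90 (SE 0.12), the histone gene H2bc4 by 0.62 and 0.57 (SE 0.10) and Kirrel3 by 0.43 and 0.33 (SE 0.13). The call of Kirrel3 ended with a second quantile normalization, with cyclic loess (0.14 and 0.05), in odor mice with the 2 groups fitted alone, and without vehicle GFP-negative replicate 4 or any odor array but GFP-negative replicate 2. In odor mice the low-activity list was called with the pool of mice as a block and without GFP-negative replicate 2 or GFP-positive replicate 3 or 4. The activity list was not called with median centring, and the low-activity list of vehicle mice was not called with a second quantile normalization.

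Immediate early genes were lower in GFP-positive cells. Of 20 such genes 17 fell and 1 rose in each treatment. Their medians were -2.12 and -2.03 (adjusted p = 2.2e-09 and 3.8e-09, and adjusted p = 0.22 and adjusted p = 0.23 with an estimated correlation). Fos was 9.16 ± 0.26 in GFP-positive and 11.81 ± 0.12 in GFP-negative cells of vehicle mice (SD, n = 3), a difference of -2.66 (SE 0.33). In odor mice the difference was -2.86 (SE 0.33). Egr2 differed by -4.07 and -3.88 (SE 0.21), Btg2, an antiproliferative gene, by -3.06 and -3.00 (SE 0.18), Fosb by -2.93 and -2.98 (SE 0.27) and Egr1 by -2.32 and -2.41 (SE 0.29). The gene that rose was Npas4, a transcription factor gene that neurons switch on, by 0.26 in vehicle mice (SE 0.09, adjusted p = 0.0288) and by 0.61 in odor mice (SE 0.09). Its vehicle call ended without replicate 1 or 2 of either vehicle group or GFP-positive replicate 4 (adjusted p up to 0.0986). Leukocyte and supporting-cell markers, given next, were also lower in GFP-positive cells. Heat shock genes fell in 4 of 9 cases in each treatment (medians -0.31 and -0.19, adjusted p = 0.011 and 0.0022, and adjusted p = 0.31 and adjusted p = 0.23 with an estimated correlation). The chaperone genes Hspa1a and Dnajb1 differed by -1.32 and -1.30 (SE 0.22) and by -1.25 and -1.41 (SE 0.14). The heat shock call held with 1 array left out, but its vehicle median was -0.15 without GFP-negative replicate 4. Its odor median was -0.08 without GFP-negative replicate 4 and -0.35 without GFP-positive replicate 3, and it was -0.10 without GFP-positive and -0.30 without GFP-negative replicate 2. Median centring and cyclic loess gave -0.16 and -0.59 in vehicle mice and -0.05 and -0.45 in odor mice.

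Leukocyte genes were far lower in GFP-positive cells. All 17 macrophage and myeloid genes fell in each treatment (medians -3.38 and -3.42, adjusted p = 1.4e-15 and 1.2e-16). So did all 12 neutrophil genes (medians -4.19 and -4.17, adjusted p = 3.3e-12 and 9.8e-13) and 9 of 10 lymphoid genes (medians -2.25 and -2.57, adjusted p = 1.9e-09 and 1.7e-10). Each of these lists had an adjusted p = 0.080 in vehicle mice and an adjusted p = 0.076 in odor mice with an estimated correlation. The neutrophil collagenase Mmp8 differed by -5.31 and -5.14 (SE 0.44), and Ifitm6 by -5.47 and -5.06 (SE 0.26). The calcium-binding S100a9 had -4.73 and -4.49 (SE 0.29) and the surface protein gene Cd24a -4.99 and -5.07 (SE 0.22). H2-Aa, which presents antigen, differed by -4.50 and -4.24 (SE 0.16), Ptprc, the common leukocyte antigen, by -4.31 and -4.27 (SE 0.16). The B cell genes Cd79a and Ms4a1 differed by -4.20 and -4.29 (SE 0.14) and by -4.76 and -4.57 (SE 0.22). In odor mice the immunoglobulin gene Igkv10-96 differed by -5.25 (SE 0.28). All 3 erythroid genes fell (medians -1.50 and -1.84, adjusted p = 0.0016 and 0.0022, and adjusted p = 0.15 and adjusted p = 0.16 with an estimated correlation). The anion exchanger Slc4a1 was among them, with -2.60 and -2.52 (SE 0.14).

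Other cells of the epithelium were also on the GFP-negative side. All 13 sustentacular genes fell in each treatment (medians -1.80 and -1.78, adjusted p = 1.2e-10 and 2.3e-11, and adjusted p = 0.11 and adjusted p = 0.096 with an estimated correlation). The sulfotransferase Sult1c1 differed by -2.67 and -2.81 (SE 0.18) and the keratin Krt18 by -2.45 and -2.50 (SE 0.13). Of 11 microvillous cell genes 10 fell (medians -1.51 and -1.59, adjusted p = 7.2e-10 and 3.0e-09), and this list kept its call with an estimated correlation (adjusted p = 0.0298 and adjusted p = 0.0380). The channel gene Trpm5 differed by -3.24 and -3.41 (SE 0.11) and the taste G protein Gnat3 by -2.25 and -2.31 (SE 0.12). Of 12 Bowman's gland genes 8 fell and 1 rose (medians -0.68 and -0.74, adjusted p = 0.0010 and 0.00080, and adjusted p = 0.15 and adjusted p = 0.14 with an estimated correlation). The transcription factor Sox9 had -2.08 and -1.88 (SE 0.08) and lysozyme Lyz1 -1.98 and -2.13 (SE 0.20), against a rise of Dcdc2a, a doublecortin domain gene, by 0.52 and 0.53 (SE 0.10). Without vehicle GFP-negative replicate 1 the list's vehicle median was -0.37. Dividing-cell and progenitor genes fell in 14 of 14 cases in vehicle mice and 13 of 14 in odor mice. Their medians were -1.20 and -1.30 (adjusted p = 5.0e-10 and 5.6e-11, and adjusted p = 0.15 and adjusted p = 0.14 with an estimated correlation), and the proliferation marker Mki67 had -3.48 and -3.72 (SE 0.17). Horizontal basal cell genes fell in 3 of 8 cases (medians -0.20 and -0.14, but -0.05 and 0.00 with median centring and -0.07 and -0.06 with a second quantile normalization, adjusted p = 0.024 and 0.045, and adjusted p = 0.31 and adjusted p = 0.39 with an estimated correlation). Icam1, an adhesion gene that leukocytes and endothelium also express, had -1.16 and -1.11 (SE 0.16), the growth factor receptor Egfr -0.79 and -0.78 (SE 0.08) and the basal keratin Krt5 -0.34 and -0.40 (SE 0.11). Krt5 lost its call with median centring in both treatments and in vehicle mice also with a second quantile normalization and without GFP-positive replicate 1 or 4 or GFP-negative replicate 4. The basal call ended in both treatments with a second quantile normalization and with cyclic loess, and in odor mice also with median centring. Cyclic loess gave an odor median of -0.23. The call ended as well without vehicle GFP-negative replicate 4 (adjusted p 0.0691), odor GFP-negative replicate 3 (adjusted p 0.114, median -0.04) or odor GFP-positive replicate 2.

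Of the underlying tissue, the glia and endothelial lists were lower, by less than the leukocyte lists, and the direction of the fibroblast list did not hold in odor mice. Ensheathing glia genes fell in 5 of 9 cases and 1 rose (medians -0.28 and -0.57, the first of them -0.13 with median centring, adjusted p = 0.0045 and 0.0039, and adjusted p = 0.080 and adjusted p = 0.076 with an estimated correlation). The receptor gene Erbb3 had -1.50 and -1.76 (SE 0.08) and Apoe, a lipid carrier, -1.54 and -1.58 (SE 0.21). The myelin gene Ncmap rose by 0.35 and 0.35 (SE 0.10), and its call ended without vehicle GFP-positive replicate 4 or odor GFP-negative replicate 4. Endothelial genes fell in 5 of 10 cases (medians -0.27 and -0.22, but -0.12 and -0.08 with median centring and -0.14 and -0.14 with a second quantile normalization, adjusted p = 0.0018 and 0.0033, and adjusted p = 0.19 and adjusted p = 0.22 with an estimated correlation). The adhesion gene Pecam1 had -1.62 and -1.60 (SE 0.12). Fibroblast genes fell in 2 of 10 cases (medians -0.16 and -0.08, but -0.01 and 0.06 with median centring and -0.03 and -0.01 with a second quantile normalization). The odor median was -0.21 with cyclic loess, 0.01 without GFP-negative replicate 3, -0.13 without GFP-negative replicate 2 and -0.15 without GFP-negative replicate 4. The 2 genes were the proteoglycan Dcn at -1.86 and -2.07 (SE 0.28) and the matrix protein Sparc at -0.92 and -0.97 (SE 0.13). The fibroblast list passed in vehicle mice (adjusted p = 0.029, and adjusted p = 0.38 with an estimated correlation) and not in odor mice (adjusted p = 0.053). Its vehicle call ended with 2 of the 3 other scalings and without vehicle GFP-positive replicate 1, and its vehicle median was -0.10 without GFP-negative replicate 4. In odor mice it was called with the pool of mice as a block and without replicate 4 of either fraction. Genes of ciliated and secretory respiratory cells split into 5 higher and 2 lower of 10 (medians 0.48 and 0.56, adjusted p = 0.28 and 0.23).

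**Figure D3:**
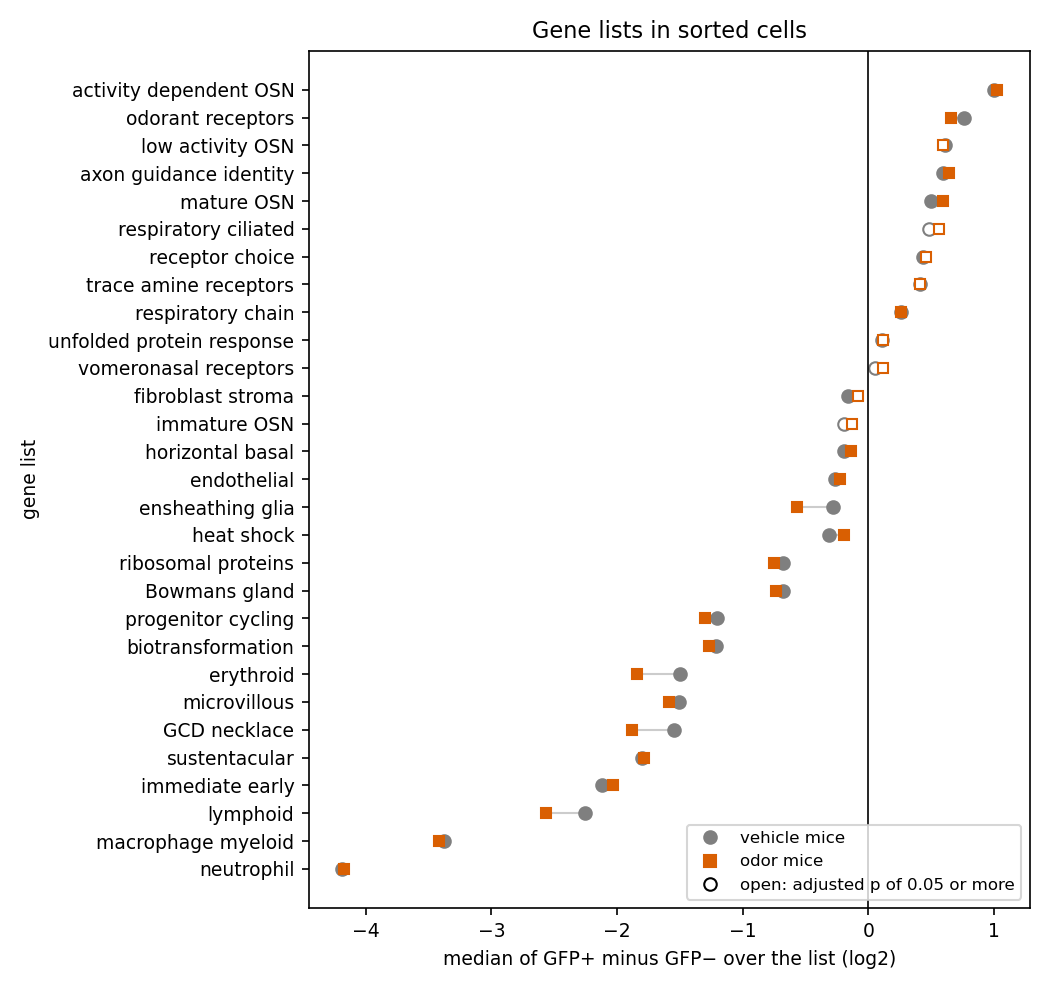
Median GFP-positive minus GFP-negative difference (log2, horizontal axis) of each of 29 gene lists (vertical axis), with circles for vehicle mice and squares for odor mice, filled where the list's adjusted p is under 0.05. The neutrophil list has the lowest medians, -4.19 and -4.17, and the activity-dependent list the highest, 1.00 and 1.02. The odor medians of the immature neuron, horizontal basal and fibroblast lists turn positive with median centring, and those of the unfolded protein response list turn negative with cyclic loess, as does the vehicle median of the vomeronasal list.

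Axon guidance and identity genes were higher in GFP-positive cells in 19 of 22 cases in vehicle mice and 20 of 22 in odor mice, and 0 fell. Their medians were 0.60 and 0.64, and 0.33 and 0.35 with cyclic loess (adjusted p = 1.2e-06 and 5.9e-06, and adjusted p = 0.24 and adjusted p = 0.27 with an estimated correlation). The ephrin receptor Epha5 rose by 1.35 and 1.37 (SE 0.14). Receptor choice genes rose in 11 of 17 cases and fell in 2 (medians 0.43 and 0.46, and 0.14 and 0.15 with cyclic loess, adjusted p = 0.047 and 0.053, and adjusted p = 0.45 and adjusted p = 0.49 with an estimated correlation). The transcription factor Emx2 had 0.77 and 0.81 (SE 0.14), the lamin B receptor Lbr -1.80 and -1.91 (SE 0.12) and the heterochromatin gene Cbx5 -0.36 and -0.29 (SE 0.09). Cbx5 lost its call with median centring and, in odor mice, with a second quantile normalization and without GFP-positive replicate 4 or GFP-negative replicate 3 or 4. This list passed with 0 of the 3 other scalings, and its vehicle call ended without vehicle GFP-positive replicate 1 or 4 or vehicle GFP-negative replicate 4 (highest adjusted p 0.0926). In odor mice it was called without GFP-negative replicate 2 or GFP-positive replicate 4. Biotransformation enzymes fell in 16 of 19 cases in each treatment, and 1 rose in odor mice (medians -1.21 and -1.27, adjusted p = 1.2e-10 and 2.3e-11, and adjusted p = 0.080 and adjusted p = 0.076 with an estimated correlation). Glutathione transferase Gstp1 had -2.47 and -2.57 (SE 0.13) and the cytochromes Cyp1a2 and Cyp2f2 had -2.59 and -2.55 (SE 0.19) and -2.11 and -2.13 (SE 0.19). The quinone reductase Nqo1, named after its values were seen, rose in odor mice by 0.29 (SE 0.11), but had -0.01 with cyclic loess. Its call also ended with a second quantile normalization, with the 2 groups fitted alone, without any odor GFP-positive array and without odor GFP-negative replicate 3 (0.19) or 4. In the guanylyl cyclase D and necklace list 12 of 16 genes fell in each treatment, 0 rose in vehicle mice and 2 rose in odor mice (medians -1.55 and -1.88, adjusted p = 2.0e-08 and 3.5e-08, and adjusted p = 0.080 and adjusted p = 0.076 with an estimated correlation). Ms4a6c, of the same family as Ms4a1, had -4.02 and -4.04 (SE 0.23). The 2 that rose, named after their values were seen, were Ms4a10 by 0.36 (SE 0.09) and Cnga3 by 0.23 (SE 0.07). Cnga3 lost its call with cyclic loess, with the 2 groups fitted alone and without odor GFP-positive replicate 3 or 4 or GFP-negative replicate 2 or 4 (adjusted p up to 0.0765).

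Ribosomal protein genes fell in 53 of 61 cases (medians -0.68 and -0.75, adjusted p = 1.8e-19 and 5.4e-22, and adjusted p = 0.15 and adjusted p = 0.14 with an estimated correlation). Rplp0 had -1.59 and -1.74 (SE 0.11) and Rps20 -1.22 and -1.27 (SE 0.13). Respiratory chain genes rose in 37 of 73 cases and fell in 3 in vehicle mice, and in 43 and 1 in odor mice. Their medians were 0.26 and 0.26 (adjusted p = 0.00024 and 0.0033, and adjusted p = 0.45 and adjusted p = 0.52 with an estimated correlation). Ndufa9, a subunit of complex I, rose by 0.61 and 0.59 (SE 0.13). Cox6b2 at -0.47 (SE 0.13) and Cox6a2 at -0.38 (SE 0.09) fell in vehicle mice, and Atp5g2 had -0.30 and -0.26 (SE 0.08), without a call with median centring or without odor GFP-positive replicate 3. With cyclic loess the list medians were 0.01 and 0.04, without a call (adjusted p 0.395 and 0.357), and with median centring 0.40 and 0.40, while a second quantile normalization gave 0.16 in vehicle mice. The unfolded protein response list did not pass (medians 0.10 and 0.11, -0.19 and -0.18 with cyclic loess, adjusted p = 0.81 and 0.80). The transcription factor Xbp1 fell by 0.48 and 0.69 (SE 0.11), while the pseudokinase Trib3 rose by 0.47 and 0.57 (SE 0.17). Trib3 had no call with cyclic loess, without replicate 1 of the vehicle arrays, replicate 4 of the vehicle arrays, odor GFP-positive replicate 2, or odor GFP-negative replicate 3 or 4. Vomeronasal receptors did not pass as a list either (medians 0.05 and 0.12, with cyclic loess -0.00 and 0.00, adjusted p = 0.62 and 0.20). Of 165, 4 were higher and 1 was lower in vehicle mice, and 17 and 0 in odor mice.

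Over all 19938 genes, limma called 5958 genes higher and 3619 lower in GFP-positive cells of vehicle mice, and 6687 and 3729 in odor mice. Groups did not overlap for 57.4% and 60.7% of genes, where chance gives 10%, and 5105 genes were higher and 3292 lower in both treatments, where independent draws would share 1998 and 677. The median of all genes was 0.06 in vehicle mice and 0.13 in odor mice, and it moved to 0.20 and 0.27 with median centring and to -0.00 and 0.00 with cyclic loess. Calls split accordingly: 9348 higher and 2844 lower with median centring and 3857 and 4942 with cyclic loess in vehicle mice, and 11702 and 3051, and 3835 and 5286, in odor mice.

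The interaction tests whether the difference between GFP-positive and GFP-negative cells was itself different in odor mice. For Olfr747 it was, by 2.17 (SE 0.24, adjusted p = 0.0186 over all genes and 0.000949 adjusted over the list alone). This fit leaves out the pairing of the fractions by pool. The call of Olfr747 over all genes ended with the pool as a block, while that over the list held. Olfr747 differed between the fractions by -0.16 (SE 0.17, adjusted p = 0.506) in vehicle mice and by 2.02 (SE 0.17, adjusted p = 1.2e-06) in odor mice. Its value in GFP-negative cells was 5.69 ± 0.13 in odor mice and 6.30 ± 0.28 in vehicle mice (SD, n = 3). Olfr292 and Olfr1208 went the other way, with interactions of -1.33 (SE 0.24) and -1.26 (SE 0.23), each at an adjusted p = 0.0462 adjusted over the list alone and 0.817 over all genes. Olfr292 differed between the fractions by -0.20 in vehicle mice and by -1.53 in odor mice, and Olfr1208 by -0.73 and by -1.99 (SE 0.17 and 0.16). In GFP-positive cells of odor mice Olfr292 lay at 4.65 to 4.90, below those arrays' lower quartiles of 5.75 to 5.78. The size of its interaction is therefore uncertain. Olfr51 at -1.04 (SE 0.28) and Olfr1308 at -0.81 (SE 0.22) did not pass.

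No gene besides Olfr747 passed over all genes in the interaction (1 in limma), and 843 had an unadjusted p under 0.05, where chance gives 996.9. Among receptors 53 did, where chance gives 50.75. That receptor count was 54 to 56 with the 3 other scalings and 81 to 113 with array weights or a replicate block. S100a5 had an interaction of 0.12 (SE 0.13), Omp of 0.01 (SE 0.11), Kirrel2 of 0.10 (SE 0.20), Kirrel3 of -0.10 (SE 0.18), Fos of -0.21 (SE 0.46) and Egr1 of -0.09 (SE 0.41). The odorant receptors as a group had a median of -0.08 (368 of 1015 above 0, adjusted p = 0.0014, and adjusted p = 0.99 with an estimated correlation), but 0.01 with array weights and -0.13 with cyclic loess. The ribosomal protein genes were lower (median -0.07, -0.03 with a second quantile normalization, 13 of 61 above 0, adjusted p = 0.0076, and adjusted p = 0.99 with an estimated correlation). The lymphoid genes did not pass as a list (median -0.10, adjusted p = 0.073). The list was called without replicate 4 of either vehicle group, odor GFP-negative replicate 2 or odor GFP-positive replicate 4. Of its genes 2 passed adjusted over the list alone, Nkg7 at -0.59 (SE 0.16) and Jchain at -0.99 (SE 0.30). Ms4a6b differed by -0.72 (SE 0.25) and the ribosomal gene Rpl7l1 by -0.25 (SE 0.11), without passing. The calls of Olfr292 and Olfr1208 ended in 11 of 17 and 14 of 18 alternatives, among them the pool of mice as a replicate block (adjusted p 0.0573 for each). Both calls ended without any 1 of the 6 odor arrays, vehicle GFP-positive replicate 4 or 1, or vehicle GFP-negative replicate 2. Olfr292 also lost its call without vehicle GFP-negative replicate 1, and Olfr1208 without vehicle GFP-positive replicate 2 or GFP-negative replicate 4 (adjusted p up to 0.140). That of Olfr747 over all genes ended with that block and with cyclic loess. It ended as well without replicate 4 of either odor group, replicate 1 of either vehicle group, vehicle GFP-positive replicate 4 or vehicle GFP-negative replicate 2. The receptor list was at an adjusted p of 0.959 without odor GFP-negative replicate 2, where its median was 0.04, and also lost its call without vehicle GFP-negative replicate 4, where its median was 0.02. The ribosomal list lost its call with a second quantile normalization and with cyclic loess. It had no call without odor GFP-positive replicate 3, odor GFP-negative replicate 4 (adjusted p 0.916), vehicle replicate 1 of either fraction or vehicle GFP-negative replicate 2. Medians with 1 array left out ranged from -0.16 (odor GFP-negative replicate 4) to 0.04 for the receptor list and from -0.12 (odor GFP-negative replicate 2) to -0.01 for the ribosomal list. Without odor GFP-negative replicate 3 the receptor median was -0.13, without vehicle GFP-negative replicate 1 -0.13 and without replicate 2 of that group -0.14. The ribosomal median was -0.12 without odor GFP-positive replicate 2, -0.02 without odor GFP-positive replicate 3, -0.03 without vehicle GFP-negative replicate 1 and -0.11 without vehicle GFP-negative replicate 4.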

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

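Of the tests given here, those of every other receptor, of a sequence variant and of the scaling between arrays were chosen only after the result was seen.

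Olfr747 stands out because its difference between GFP-positive and GFP-negative cells itself differed between odor and vehicle mice, by 2.17 (SE 0.24, adjusted p = 0.000949 adjusted over the list alone). Olfr747 was called over the list but not over all genes with the pool of mice as a replicate block. In GFP-positive cells it was higher by 1.57 (SE 0.17) in odor mice, where each of 3 odor arrays lay above each of 3 vehicle arrays. Signal from another receptor bound by the same probes would need that receptor to rise as much, if its own probe set responds as fully. Whether it does was not tested. Among 12 other measured receptors of its sequence family the highest rise was 0.34 (Olfr736, SE 0.27), and among all other receptors 0.80 (Olfr460, SE 0.34). Olfr747 had the largest rise of all receptors, so lower rises elsewhere were fixed by its choice, and only the size of the gap can count. For the family the gap was wide, which argues against a measured relative whose own probe set responds as fully. For Olfr460 it was barely past 2 standard errors, and no conclusion is drawn. The 10 measured receptors nearest to Olfr747 on its chromosome differed by -0.62 to 0.08. A sequence variant carried by the odor mice would raise both fractions, whereas Olfr747 differed by -0.61 (SE 0.17) in GFP-negative cells. That direction goes against a variant, but the value was seen before the explanation was put and had no call, so no conclusion is drawn. The scaling between arrays is argued against by a lowest rise of 1.54 under 3 other scalings (highest adjusted p 0.00284 adjusted over the list alone).

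What stays open for Olfr747 includes a sequence variant and signal from a measured receptor outside its family. A relative whose own probe set responds less stays open too. So does signal from a receptor without a named probe set, although the highest rise among 13767 probe sets without a single gene name was 1.43. For the interaction the highest value among them was 2.38, above the 2.17 of Olfr747, with 0 of them called. The 10 splits of the 6 GFP-positive arrays are too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes were called (1 real, 0 highest other), and in 1 of 10 as many receptors (2 real, 1 highest other). For the interaction, 2 of 10 splits of the pools called as many genes (1 real, 1 highest other) and 3 of 10 as many receptors (3 real, 28 highest other), again too few for a share under 0.05. A candidate biological explanation is that the accord activates neurons with Olfr747, which then enter the GFP-positive fraction and leave the other. This was not tested: the value of -0.61 in GFP-negative cells goes the way it would need, but was seen before the explanation was put, and the 6 pools offer no separate exposure to decide it.

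The other results with a difference between odor and vehicle mice in the same test are given as values. Olfr292 had an interaction of -1.33 (SE 0.24), from -0.20 in vehicle mice to -1.53 in odor mice. Olfr1208 had an interaction of -1.26 (SE 0.23), from -0.73 to -1.99. These calls ended in 11 of 17 and 14 of 18 alternatives. The odorant receptors as a list had a median interaction of -0.084 (368 of 1015 above 0, adjusted p = 0.0014, and adjusted p = 0.99 with an estimated correlation), but 0.0053 with array weights, 0.018 without vehicle GFP-negative replicate 4 and 0.040 without odor GFP-negative replicate 2. Ribosomal protein genes had a median interaction of -0.067 (13 of 61 above 0, adjusted p = 0.0076, and adjusted p = 0.99 with an estimated correlation), and between -0.12 and -0.013 with 1 array left out.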

How the results depend on the processing

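Of the alternatives given here, cyclic loess for the list tests and the GFP-positive arrays alone with the code number as block were chosen only after the data were seen. In all, 246 values were recomputed under their alternatives, which gave 3260 values. Of these 3123 kept their direction and their side of the threshold, 91 kept their direction but lost the call, 8 gained a call and 38 changed direction. Changes were in 42 of the 246 values, and where no cause is given the cause was not tested. The sort called 8357 to 12192 genes in vehicle mice and 8663 to 14753 in odor mice over the alternatives, against 9577 and 10416, and 585 to 807 and 540 to 794 receptors, against 742 and 730. In vehicle mice S100a5 gained a call with a second quantile normalization (0.29) and with median centring (0.34), against 0.19. Olfr618 gained one in GFP-positive cells without odor replicate 2, and Nkg7 in GFP-negative cells without odor replicate 2.

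The list tests changed with the correlation assumed between genes. With an estimated correlation 0 lists were called in GFP-positive cells instead of 4, 0 in GFP-negative cells instead of 8, 1 for the sort in vehicle mice instead of 24, 1 in odor mice instead of 21 and 0 in the interaction instead of 2. An estimated correlation makes the test of a correlated list stricter by construction. With fry 0 lists were called in GFP-positive cells, 0 in GFP-negative cells and 0 in the interaction, and fry asks another question. It called 27 and 28 lists for the sort.

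With a second quantile normalization the interaction had 1 list, and Kirrel3 in GFP-negative cells had -0.0038. With median centring 1 named gene changed sign for odor minus vehicle in GFP-positive cells: Omp had -0.0034. The median of all genes turned there too, to -0.0047 from 0.0044. So did the medians of the ensheathing glia (-0.0082), fibroblast (-0.0052) and vomeronasal (-0.0056) lists, none of them called. With cyclic loess 0 genes were called in GFP-positive cells and 0 in the interaction, lists numbered 3 in GFP-negative cells and 1 in the interaction, and in GFP-negative cells Omp had 0.049 and Kirrel2 0.0056. In the interaction cyclic loess gave -0.0046 for S100a5 and -0.040 for Omp. With array weights Kirrel2, Kirrel3 and Fos had 0.0085, -0.052 and 0.046 in GFP-negative cells, and Olfr1204 gained a call in GFP-positive cells. The genes of these changed signs had no call under either setting. For the sort in odor mice Nqo1, which had a call at 0.29, had -0.011 with cyclic loess. With array weights the median receptor turned to -0.075 in GFP-negative cells, against 0.036, and to 0.0053 in the interaction, against -0.084.

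With the filter on the genes lowest in value 1 receptor was called in GFP-positive cells and 1 in the interaction, and 2 lists in GFP-negative cells. That filter removed Olfr1280, Olfr1204 and Olfr292, which therefore have no value under it. With the filter at the table median 1 receptor was called in GFP-positive cells and 1 in the interaction, where fewer genes were tested. With receptors centred on their own median the counts were 1 and 1 as well, and the sort had 258 higher and 327 lower in vehicle mice and 257 and 283 in odor mice, by construction. With the 2 groups alone 0 genes and 1 receptor were called in GFP-positive cells, from fewer arrays for the spread. With a threshold of 0.10, 2 receptors were called in GFP-negative cells by construction.

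Replicate blocks pair the arrays, but by title number odor replicate 3 and vehicle replicate 1 have no partner of the other treatment. With the title number as block 0 genes were called in GFP-positive cells, 4 receptors in GFP-negative cells (Olfr994, Olfr1198, Olfr1243 and Olfr895, named after their values were seen) and 1 receptor in the interaction, and the median receptor turned to 0.011 in GFP-positive cells, against -0.051. With the pool of mice as block the interaction had 0 genes and 1 receptor. With the code number as block in GFP-positive arrays alone 0 genes and 5 receptors were called: Olfr814, Olfr747, Olfr183, Olfr1284 and Olfr1200, of which 1 is shared with the 2 called without the block. With the code number in all arrays 1 gene and 2 receptors were called in GFP-positive cells, 0 and 0 in GFP-negative cells and 1 and 2 in the interaction. With the pool as a random block, at a correlation of 0.110, these were 1 and 2 in GFP-positive and 0 and 0 in GFP-negative cells. For the sort the pool block gave 9513 genes and 784 receptors in vehicle mice and 10243 and 773 in odor mice. The code block gave 9756 and 767, and 10554 and 752, and the title block 9655 and 772, and 10481 and 766. No other count of genes, receptors or lists moved by more than 1.5 times with a block.

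Leaving out 1 array left 2 in its group. In GFP-positive cells this gave 0 to 1 genes, 1 to 3 receptors and 1 to 5 lists, with 0 genes without odor replicate 3 or 4 or vehicle replicate 1 or 4. Receptors numbered 1 without odor replicate 4 or vehicle replicate 1 or 2 and 3 without vehicle replicate 4. Lists numbered 1 without odor replicate 4 and 5 without odor replicate 3. In GFP-negative cells it gave 0 to 15 genes, 0 to 5 receptors and 2 to 13 lists. Without odor replicate 2 the counts were 15, 5 and 13, without odor replicate 3 they were 3, 2 and 4, and without odor replicate 4 they were 1, 1 and 2. Without vehicle replicate 1, 1 receptor and 4 lists were called, without vehicle replicate 2, 6 lists, and without vehicle replicate 4, 2 receptors and 11 lists. The interaction had 0 to 3 genes, 1 to 3 receptors and 1 to 8 lists, with 3 genes without odor GFP-negative replicate 3, 8 lists without vehicle GFP-positive replicate 4, and 7 without odor GFP-negative replicate 2 or odor GFP-positive replicate 4.

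The ranges with 1 array left out crossed 0 for marker genes that had no call in any of these fits. In GFP-positive cells Fos lay between -0.60 and 0.19, Egr1 between -0.49 and 0.18, S100a5 between -0.034 and 0.062 and Omp between -0.010 and 0.022, and Fos and Egr1 were above 0 without odor replicate 2. In GFP-negative cells Kirrel3 lay between -0.11 and 0.15, Fos between -0.24 and 0.13, Egr1 between -0.27 and 0.043, Omp between -0.074 and 0.047 and Kirrel2 between -0.10 and 0.12. In the interaction Fos lay between -0.52 and 0.28, Egr1 between -0.34 and 0.33, Kirrel3 between -0.21 and 0.045, Omp between -0.041 and 0.080 and Kirrel2 between -0.030 and 0.23. Signal over background limits the weak probe sets: the lowest value of any array was 2.42 and none is at 0, so the absence of a transcript cannot be read from these values.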

Other observations

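Of the tests given here, those of a lower share of neurons and of receptors in both fractions were chosen only after the result was seen, as were Gap43, Dcx, Tubb3 and, in odor mice, Foxj1.

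Genes of immature neurons went in opposite directions within their list. In GFP-positive cells Dcx, a microtubule gene of young neurons, was higher by 0.67 in vehicle mice and 0.62 in odor mice (SE 0.11), and the neuronal tubulin Tubb3 by 0.75 and 0.69 (SE 0.14). The growth cone gene Gap43 fell by 0.74 and 0.62 (SE 0.12), and Gng8, a G protein subunit of immature neurons, had -1.23 and -0.90 (SE 0.14). The chemokine receptor Cxcr4, which leukocytes also express, had -3.61 and -3.80 (SE 0.22), and Marcksl1 had -1.46 and -1.77 (SE 0.17). Respiratory cell genes split likewise. The cilium genes Foxj1 and Ccdc39 were higher by 0.62 and 0.66 (SE 0.11) and by 0.85 and 0.93 (SE 0.13). The secreted proteins Reg3g and Bpifa1 had -1.15 and -1.15 (SE 0.18) and -1.03 and -1.24 (SE 0.22).

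Class I receptors, counted here as those of sequence families numbered up to 42, were enriched less in GFP-positive cells than class II receptors. The class I median minus the class II median was -0.245 on average over 6 pools (SD 0.0592, range -0.296 to -0.153), below 0 in 6 of 6 pools. The exact sign permutation p was 0.03125, two-sided, the smallest that 6 pools can give. Within treatments the gap was -0.229 in vehicle and -0.260 in odor pools, and with a second quantile normalization and cyclic loess it was -0.202 and -0.197. Adjusted over the list alone, 65 of 117 class I receptors were higher and 10 lower in vehicle mice, and 57 and 10 in odor mice. Of 884 class II receptors 552 were higher and 104 lower, and 534 and 120. Class I receptors also had lower median values than class II, 7.22 against 7.70 in GFP-positive and 6.72 against 6.87 in GFP-negative cells. For 14 receptors no class could be assigned. No explanation for the gap was tested.

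Immediate early genes were lower in GFP-positive cells by medians of -2.12 and -2.03 in vehicle and odor mice, and leukocyte and sustentacular genes were lower too. These genes may lie lower because leukocytes in the GFP-negative fraction carry the transcripts. Over the 6 GFP-negative arrays the mean of the immediate early genes went with the mean of 39 leukocyte genes with a Pearson r of 0.728 (permutation p 0.0778, adjusted 0.156) and a Spearman rho of 0.886 (permutation p 0.0333, adjusted 0.0667). Without the 2 arrays farthest from the median r was 0.772, and after removal of group means 0.940. For 13 sustentacular genes r was 0.478 (permutation p 0.324, adjusted 0.324) and rho 0.143 (permutation p 0.803, adjusted 0.803), and r was 0.211 without the 2 farthest arrays. These 2 relations were the family tested. Neither excludes nor settles its explanation, since no p passed after adjustment. The leukocyte genes averaged 10.4 to 10.9 in these arrays. Those of highest signal, Lcn2, Ngp and Cd74, had means of 13.4, 13.3 and 12.9 in GFP-negative cells of vehicle mice. Signals of different probe sets do not rank abundance, so these values do not bear on the source of the transcripts. The labels name no gate that removes leukocytes. Differences between neurons with and without the reporter, and a response to dissociation, were not tested and stay open too.

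The macrophage, neutrophil and lymphoid lists were called in GFP-negative cells of odor mice, but each had an adjusted p = 0.86 with an estimated correlation. Their 39 genes differed by a mean of 0.193 (SE 0.165), within 2 standard errors of 0, so that a rise is itself not shown, while 34 sustentacular, microvillous and endothelial genes differed by -0.00810 (SE 0.0748). A lower share of sensory neurons would raise both alike only if the other cells kept their proportions, which was not tested. The gap between them was 0.201 (SE 0.169), within 2 standard errors of 0, so a lower neuron share could neither be excluded nor shown. A single pool could decide the shift: the lowest difference with 1 array left out was 0.0706 (SE 0.143, without odor GFP-negative replicate 4) and the highest 0.332 (SE 0.116, without odor GFP-negative replicate 2). Odor exposure, which the design names, was not tested apart from these 6 pools and stays open.

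Between odor and vehicle in GFP-negative cells 0 genes and 0 receptors were called. Any split gives at least 0, so the counts of 10 of 10 splits for genes and 10 of 10 for receptors were fixed beforehand and test nothing. The highest other split called 1939 genes and 128 receptors, which points to a structure of these samples. It set odor replicate 2 with vehicle replicates 1 and 2 against odor replicates 3 and 4 with vehicle replicate 4. Receptor medians were 7.23, 7.00 and 7.00 in the former arrays and 6.76, 6.73 and 6.61 in the latter. Leukocyte means followed the same split, with 10.4, 10.4 and 10.4 in the former and 10.7, 10.9 and 10.6 in the latter, whereas sustentacular means did not (10.1, 10.3 and 10.4, and 10.4, 10.3 and 10.1). The labels name no batch that follows it. For the sort in vehicle mice 1 of 10 splits called as many genes (9577 real, 0 highest other) and 1 of 10 as many receptors (742 real, 0 highest other). For the sort in odor mice the numbers were 1 of 10 for genes (10416 real, 0 highest other) and 1 of 10 for receptors (730 real, 2 highest other). All of these splits are too few for a share under 0.05.

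Receptor transcripts gained by the GFP-positive fraction of odor mice may be lost from the GFP-negative fraction. Across 1015 receptors, which are not independent replicates, the odor differences in the fractions had a Pearson r of -0.0195 and a Spearman rho of 0.0130. Among 10 splits of the pools 1, the real one, gave an r as low, and the others lay between 0.0580 and 0.285. The splits are too few for a share under 0.05, and r and rho differ in sign, so the hypothesis stays open.

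Among the 13767 probe sets without a single gene name, limma called 0 between odor and vehicle in GFP-positive cells, 0 in GFP-negative cells and 0 in the interaction. Unadjusted p-values under 0.05 numbered 259, 715 and 648. Between the fractions 713 were higher and 929 lower in GFP-positive cells of vehicle mice, and 837 and 1013 in those of odor mice.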
